A study of Mus musculus with 48 samples.

How the data were processed

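Liver RNA from 24-week-old female mice was sequenced in 48 libraries. The mice came from the 8 founder strains of the Diversity Outbred and Collaborative Cross populations and ate 1 of 2 diets, with 3 mice per strain and diet. Per the labels, frozen liver was extracted with a Maxwell 16 kit, libraries followed the TruSeq protocol from total RNA, and reads were aligned with STAR 2.7.0f to the mouse build GRCm38. The read counter, its strand setting and the normalization tool are not given in the sources used here.

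The deposited table holds 1 value for each of 55413 genes in each library. Its unit is a normalized signal made by the authors, which the values show to be whole reads per gene divided by an effective library size in units of 1e+06. Of the values above 0, 100% were whole multiples of the smallest value of their library, within 0.001 read. Recomputed trimmed-mean-of-M (TMM) factors matched the implied factors within 1e-15, so the deposited values equal counts per 1e+06 reads (CPM) with TMM scaling. All 55413 identifiers matched symbols of a reference annotation of GRCm38, which also gave the positions printed here. Mitochondrial genes were not analysed here. Of the symbols, 109 stand for more than 1 gene model.

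Recovered reads in genes, in units of 1e+06, ran from 12.5 to 26.8 per library. They averaged 17.5 ± 3.90 (SD, n = 24) on AIN-93M and 17.9 ± 2.30 (SD, n = 24) on the high fat/cholic acid diet. 1 read stood for a value of 0.0392 to 0.0838. Between replicates of a group, the spread of reads was 8.25 to 133 times the counting variance over 48 pairs. This spread holds differences of mice, dissection, extraction and library preparation alike, and the highest ratios include libraries that stood apart. Depth limits statements about genes near 0.

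Groups were the 16 combinations of strain and diet. Genes needed a value of at least 10 in at least 3 libraries, which left 10917. The test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 mean per group, 32 residual degrees of freedom and an empirical Bayes spread that follows the level. P-values were adjusted by Benjamini-Hochberg within each contrast at 0.05. Contrasts were the diet difference averaged over the 8 strains, the diet difference within each strain, the F test of the diet-by-strain interaction, and each strain's diet difference against the mean of the other 7. Strain F tests on each diet, and each strain against the other 7 on AIN-93M, completed them. Standard errors (SE) come from this fit. They rest on 1 spread per gene shared by all 16 groups and do not measure the spread within a single strain. Because 1 was added before the log, a log2 change of a gene near 0 on 1 diet is smaller than the ratio of its means.

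The 33 gene lists (642 symbols, 639 in the table, 524 tested) were written from textbook knowledge before the data were examined, and 29 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, and with limma on the mean log2 value of the list in each library. The last of these tests was chosen after seeing the data. Lists of muscle, adrenal, female-biased and male-biased genes were also chosen after seeing the data, and the members of the last pair all come from a list fixed beforehand.

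The rule for named genes was fixed before the data were examined as well. For the averaged diet effect it takes the 5 largest increases and 5 largest decreases among genes past the threshold with a mean value of at least 100 and the same sign in all 8 strains. It adds the 2 members of each list with the smallest adjusted p and a fixed panel of 20 genes, not all of which are reported. Within each strain it takes the largest increase and decrease, for the interaction the 10 smallest p, and for each strain on AIN-93M the largest difference each way, all at a mean of at least 100. Nnt, Xist and Ddx3y were fixed as checks of the labels. Genes named outside the rule were chosen after their values were seen, namely Scd2, Cyp3a11, Hamp, Hsd3b5, Mup20, Cyp4a12a, Cyp7b1, Elovl3, Hba-a2, the list members named where few went against their list, and the genes of adrenal, muscle, pancreas and adipose tissue in the closing section. Several named genes belong to families with nearly identical members (Cyp3a, Cyp2b, Cyp2c, Cyp4a, Mup, Serpina1, Saa, Sult, Ugt2b, Gst and globin genes). Reads of all strains were aligned to 1 reference build, so the split of reads within such a family is uncertain.

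The method was tested on simulated data with genes changed by known folds. At 1.5-fold, limma recovered 88.1% of 67 genes for the averaged diet contrast and 55.2% for the contrast within AJ. At 2-fold these shares were 100% and 89.6%, with 5.42% false calls for the averaged contrast. The interaction test recovered 22.4% at 1.5-fold and 64.2% at 2-fold, with 7.14% false calls. For the averaged contrast edgeR made 6.73% and DESeq2 12.2% false calls. A planted list was found by camera and by list means, and 0 of 28 random lists were. The simulated genes were drawn independently of each other, so this cannot test false calls among correlated genes. In the data the lists had estimated correlations from 0.0587 to 0.857. With diet reassigned within strains, camera at the preset correlation called a median of 8 of 29 lists. The simulation also changed few genes (67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold), unlike the data.

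Alternatives were pseudocounts of 0.5 and 5, no filter, a filter of a mean of at least 50, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust empirical Bayes and each library left out in turn. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered whole reads, and each strain's contrast also on its own 6 libraries. Chosen after seeing the data were plain CPM, a filter of at least 1 in at least 3 libraries, and a fit without 4 libraries that stood apart (B6 replicate 1, CAST replicates 2 and 3 and PWK replicate 3 on high fat/cholic acid). The last of these fits keeps 2 libraries of B6, 1 of CAST and 2 of PWK on that diet. No label gives a batch. The sample numbers run from 1 to 76 on high fat/cholic acid and from 703 to 763 on AIN-93M. If these numbers mark separate processing, batch and diet cannot be told apart. Within each diet the numbers also run in separate blocks by strain, so the same holds for strain effects and the interaction if processing followed these blocks.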

Results

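Gene expression was measured by RNA-seq in the livers of female mice from 8 inbred strains at 24 weeks of age. The strains were A/J (AJ), C57BL/6J (B6), 129S1/SvlmJ (129), NOD/ShiLtJ (NOD), NZO/HILtJ (NZO), CAST/EiJ (CAST), PWK/PhJ (PWK) and WSB/EiJ (WSB). Mice ate AIN-93M or a diet with high fat and cholic acid (HFCA), with 3 mice of each strain and diet. Recovered reads per library, in units of 1e+06, ran from 12.5 to 26.8. Values are TMM-scaled CPM, changes are log2 differences of HFCA minus AIN-93M, and errors are SE. Averaged contrasts rest on n = 24 + 24 libraries and contrasts within a strain on n = 3 + 3. Sample numbers part the diets fully. If they mark separate processing, batch and diet cannot be told apart in the averaged and within-strain diet results. A shift shared by all strains of a diet would cancel in comparisons of diet changes between strains. Within each diet, however, the numbers run in separate blocks by strain. A shift of single blocks would not cancel, and could not be told apart from strain effects or the interaction.

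Strain accounted for the largest share of variation in liver expression, ahead of diet. The median share of a gene's variation was 45.1% for strain, 11.4% for diet, 10.4% for their interaction and 21.01% for mice of the same group. With no effects at all, these shares would be near 14.9%, 2.13%, 14.9% and 68.1%. Strain was the largest term for 7064 of the 10917 genes tested and diet for 2105. Among genes with a mean of at least 100, the median share of diet was 17.3%. All 48 libraries had their nearest neighbour in their own strain, and 46 had it in their own group. The exceptions were B6 HFCA replicate 1 and CAST HFCA replicate 3, which lay nearest to AIN-93M libraries of their strains.

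**Figure D1:**
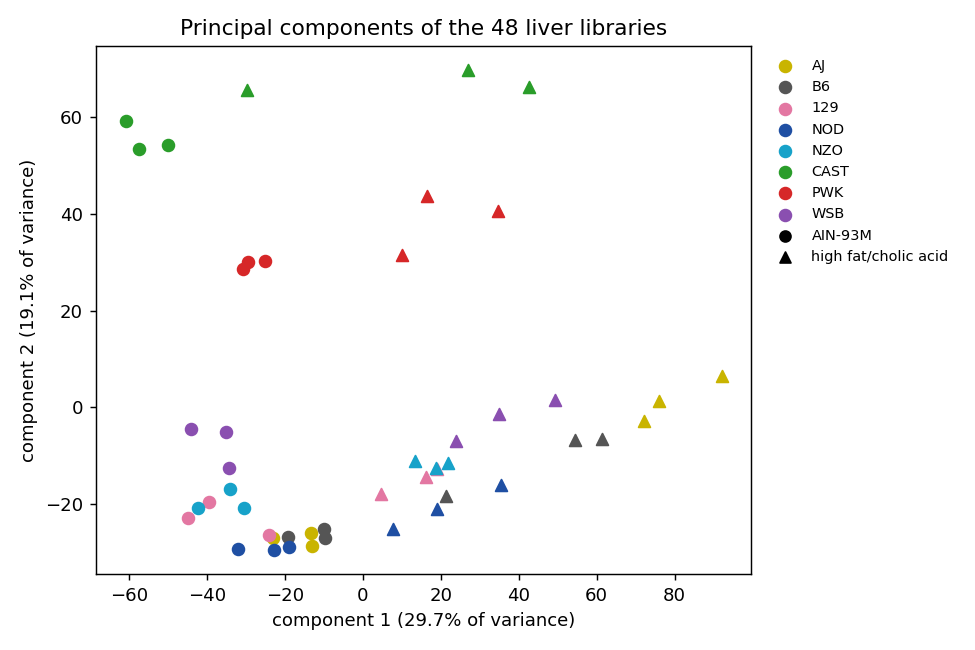
Principal components of log2(value + 1) for 10917 genes in 48 libraries, with colours for strains, circles for AIN-93M and triangles for HFCA. Component 1 (29.7% of variance) parts the diets within each strain and component 2 (19.1%) sets CAST and PWK apart from the other strains.

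The first comparison asked which liver genes differ between the diets across the 8 strains. Genes of macrophages, inflammation and matrix were higher on HFCA, while those of cholesterol synthesis and lipogenesis were lower. The largest increase was in Gpnmb, a glycoprotein of lipid-laden macrophages (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929). Its mean rose from 1.27 to 570, a log2 change of 7.39 ± 0.31 (adjusted p = 1.30e-19) that passed the test in 8 of 8 strains. Lcn2, an acute phase protein (chromosome 2, 32384633 to 32388252), rose by 4.39 ± 0.29, and Lpl, which hydrolyses lipoprotein triglyceride (chromosome 8, 68880491 to 68907448), by 3.95 ± 0.23. Lyz2, the lysozyme of myeloid cells (chromosome 10, 117277331 to 117282321), rose by 3.38 ± 0.19, and the metalloprotease family member Adam11 (chromosome 11, 102761439 to 102780262) by 3.04 ± 0.16.

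Among genes with a mean of at least 100 and the same sign in all 8 strains, the largest decreases were in genes of hepatocytes. Cyp3a44, a female-biased cytochrome P450 (ENSMUSG00000054417.5, chromosome 5, 145773983 to 145805874), went from a mean of 426 to 56.2, with a log2 change of -5.29 ± 0.34 averaged over strains and a decrease in 8 of 8. Its HFCA mean is carried by CAST, at 369 ± 554 (SD, n = 3), against at most 33.5 in the other strains. The serpin pseudogene Serpina4-ps1 (chromosome 12, 104080649 to 104086724) changed by -5.21 ± 0.39, also in 8 strains. Cyp3a41a (chromosome 5, 145694049 to 145720136) changed by -3.72 ± 0.27, the sulfotransferase gene Sult3a1 (chromosome 10, 33857721 to 33879532) by -3.66 ± 0.27 and the plasma glycoprotein gene A1bg (chromosome 15, 60896859 to 60923012) by -3.50 ± 0.33. Reads of the Cyp3a genes cannot be fully told apart, and Cyp3a11 rose by 1.75 ± 0.14. In all, 7848 of 10917 genes passed the test by limma, 3462 higher and 4386 lower, of which 766 and 225 changed at least 2-fold. The split by direction depends on the scaling. With plain CPM the median change of all genes was 0.14 instead of -0.04, and 5814 genes were higher and 2189 lower. Without the 4 HFCA libraries that stood apart 8066 genes passed, 7624 of them among the 7848.

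Genes of cholesterol synthesis fell together. All 26 list members fell, with a mean change of -1.50 ± 0.07 (camera adjusted p = 2.76e-14; adjusted p = 0.192 with an estimated correlation). The sterol demethylase gene Cyp51 (-2.43 ± 0.11), the sterol reductase gene Tm7sf2 (-2.21 ± 0.10) and Sqle, which encodes squalene epoxidase (-3.03 ± 0.15), were among them. Of 14 genes of the oxysterol receptor LXR and its targets 8 rose and 2 fell, namely Nr1h3 and Nr1h2 (camera adjusted p = 0.00298; adjusted p = 0.192 with an estimated correlation). The sterol exporter genes Abcg1 (2.82 ± 0.16), Abca1 (0.60 ± 0.06) and Abcg5 (0.83 ± 0.06) were among those that rose.

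Bile acid genes were lower in synthesis and mixed in transport. Of 16 synthesis genes 13 fell and 0 rose (camera adjusted p = 0.00374; adjusted p = 0.361 with an estimated correlation, 0.269 under quantile normalization and 0.0807 at a mean of at least 50). Cyp8b1, the sterol 12-alpha-hydroxylase that makes cholic acid, fell by 3.04 ± 0.29, and Akr1c6, a ketosteroid reductase gene, fell by 0.66 ± 0.06. Cyp7a1, the rate-limiting enzyme, had a change of 0.48 ± 0.25 that did not pass the test (adjusted p = 0.0832). It passed under quantile normalization (0.61, adjusted p = 0.0289), with plain CPM (0.67, adjusted p = 0.0162) and without B6 HFCA replicate 2 (0.57), NOD AIN-93M replicate 3 (0.58) or PWK HFCA replicate 3 (0.57). Among 17 genes of bile acid transport and the receptor FXR 12 fell and 3 rose, namely Abcc4, Abcc3 and Slc10a2 (camera adjusted p = 0.0530). The uptake carrier gene Slc10a1 fell by 1.70 ± 0.11 in 8 of 8 strains. Abcc4, an exporter toward blood, rose by 1.81 ± 0.12 on average but fell in PWK (-1.30). Nr0b2, an FXR target, fell by 0.55 ± 0.12, and the canalicular pump gene Abcb11 fell by 0.41 ± 0.10 but did not pass under quantile normalization (-0.09, adjusted p = 0.355).

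Genes of fat synthesis were lower on average, while the result for fat oxidation depends on the scaling. In the lipogenesis list 20 of 24 members fell and 1, the desaturase gene Scd2 (2.47 ± 0.18), rose (camera adjusted p = 3.46e-05; adjusted p = 0.192 with an estimated correlation). The lipogenic regulator Thrsp fell by 2.53 ± 0.13, Acss2, which makes acetyl-CoA from acetate, fell by 2.20 ± 0.16 and the fatty acid synthase gene Fasn fell by 1.27 ± 0.16. The desaturase gene Scd1 changed by -0.08 ± 0.13 (adjusted p = 0.581), and by 0.24 under quantile normalization and 0.11 with plain CPM. Of 36 genes of fatty acid oxidation under PPAR-alpha 23 fell and 3 rose, namely Pdk4, Acot2 and Ehhadh (camera adjusted p = 0.00712; adjusted p = 0.526 with an estimated correlation, 0.557 under quantile normalization and 0.196 at a mean of at least 50). The list mean of -0.29 ± 0.08 was -0.10 under quantile normalization (adjusted p = 0.112) and -0.10 with plain CPM (adjusted p = 0.129). The fatty acid binding protein gene Fabp1 fell by 1.02 ± 0.08 and the thiolase gene Acaa2 fell by 0.58 ± 0.06. Cpt1a, which admits fatty acids to mitochondria, changed by -0.04 ± 0.09 (adjusted p = 0.732), but by 0.28 under quantile normalization (adjusted p = 0.000660) and 0.15 with plain CPM (adjusted p = 0.0726). Cyp4a14, a PPAR-alpha target, changed by -0.44 ± 0.27 (adjusted p = 0.138), and by -0.56 without CAST HFCA replicate 3 (adjusted p = 0.0391).

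Lipid droplet genes went both ways, while apolipoprotein and glucose genes were mostly lower. In the droplet list 8 of 15 members rose and 4 fell, namely G0s2, Cideb, Abhd5 and Fitm2 (camera adjusted p = 0.126). The fatty acid receptor gene Cd36 rose by 1.29 ± 0.08 and the droplet coat gene Plin3 by 0.52 ± 0.06. Plin2, the main coat of hepatocyte droplets, changed by 0.17 ± 0.11 (adjusted p = 0.163). It passed under quantile normalization (0.48, adjusted p = 2.56e-05), with plain CPM (0.36, adjusted p = 0.00162) and without CAST AIN-93M replicate 3 (0.24, adjusted p = 0.0154). Of 24 apolipoprotein and lipoprotein genes 18 fell and 2 rose, namely Scarb1 and Sort1 (camera adjusted p = 0.00426; adjusted p = 0.364 with an estimated correlation, 0.304 under quantile normalization and 0.0520 at a mean of at least 50). Apom fell by 0.87 ± 0.07 and Apoc3, an inhibitor of triglyceride clearance, fell by 0.68 ± 0.06. Of 21 genes of glucose metabolism 16 fell and 1, Pfkl, rose (camera adjusted p = 0.000206; adjusted p = 0.192 with an estimated correlation). The pyruvate kinase gene Pklr fell by 1.30 ± 0.10 and the glycogen phosphorylase gene Pygl fell by 0.64 ± 0.05. The 100 most abundant genes on AIN-93M had a median change of -0.48 (5% to 95% of them -1.02 to 0.13). The list means of apolipoproteins (-0.32 ± 0.04), glucose metabolism (-0.53 ± 0.05), bile acid synthesis (-0.54 ± 0.07) and fatty acid oxidation (-0.29 ± 0.08) were not tested against the changes of abundant genes. The sizes of these means depend on the scaling, as the median change of all genes was 0.14 with plain CPM instead of -0.04.

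Macrophage and inflammatory genes rose. Of 25 macrophage and Kupffer cell markers 24 rose and 0 fell, by 2.46 ± 0.14 on average (camera adjusted p = 9.59e-14; adjusted p = 0.192 with an estimated correlation). The macrophage elastase gene Mmp12 rose by 5.32 ± 0.24 and the lipid-sensing receptor gene Trem2 by 3.89 ± 0.25, from a mean of 0.760 to 36.8. All 17 tested genes of NF-kappaB and cytokines rose (camera adjusted p = 7.33e-09; adjusted p = 0.192 with an estimated correlation), among them the adhesion molecule Icam1 (1.62 ± 0.10), the pattern receptor Tlr2 (2.53 ± 0.16) and the monocyte attractant Ccl2 (2.76 ± 0.18). All 8 MHC class II genes rose (camera adjusted p = 8.58e-07; adjusted p = 0.192 with an estimated correlation), with H2-Aa at 2.56 ± 0.16 and the invariant chain Cd74 at 2.45 ± 0.16. Of 27 acute phase genes 16 rose and 10 fell (camera adjusted p = 0.0160; adjusted p = 0.456 with an estimated correlation and 0.130 with plain CPM). The serum amyloid genes Saa3 (2.67 ± 0.16) and Saa1 (2.60 ± 0.20) rose, whereas the hepcidin gene Hamp fell by 1.18 ± 0.32. Of 26 interferon response genes 24 rose and 1, Stat2, fell (camera adjusted p = 5.98e-06; adjusted p = 0.333 with an estimated correlation), with the antiviral genes Oas1a at 1.67 ± 0.10 and Oasl2 at 1.27 ± 0.12.

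Few markers of other immune cells were above the filter. The 4 B and plasma cell markers tested rose (camera adjusted p = 0.00712; adjusted p = 0.192 with an estimated correlation), with the B cell receptor regulator Cd22 at 1.90 ± 0.11 and Cd37 at 1.25 ± 0.11. Of 22 T and NK cell markers 1 was tested, the interleukin-7 receptor gene Il7r (2.49 ± 0.20), and of 15 neutrophil markers 2 were, Csf3r (2.09 ± 0.17) and S100a9 (1.74 ± 0.15). These lists had too few members for a list test at this filter. They passed without a filter (adjusted p = 6.34e-12 and 2.60e-07) and with the filter of at least 1 (1.27e-06 and 0.000547).

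Matrix, ductal and proliferation genes also rose. Of 29 stellate cell and fibrosis markers 27 rose and 0 fell (camera adjusted p = 1.36e-09; adjusted p = 0.252 with an estimated correlation). Col1a1, a chain of type I collagen, rose by 3.52 ± 0.30, the protease inhibitor gene Timp1 by 2.71 ± 0.19 and the stellate cell receptor gene Pdgfrb by 1.36 ± 0.11. Of 15 cholangiocyte and ductular markers 10 rose and 1, Onecut1, fell (camera adjusted p = 0.00749; adjusted p = 0.333 with an estimated correlation and 0.0609 with plain CPM). They include the keratin genes Krt8 (1.42 ± 0.12) and Krt18 (1.10 ± 0.11), which hepatocytes also express. Of 14 proliferation genes 11 rose and 2 fell, namely Tk1 and Tyms (camera adjusted p = 0.00298; adjusted p = 0.333 with an estimated correlation). The replication licensing genes Mcm2 (1.31 ± 0.10) and Mcm6 (1.29 ± 0.14) rose. Of 17 sinusoidal endothelial markers 4 rose and 7 fell (camera adjusted p = 0.441), and the list mean of -0.12 was 0.06 with plain CPM. Bmp2, a regulator of iron, fell by 0.49 ± 0.07 and the lectin gene Clec4g fell by 0.44 ± 0.08.

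Stress and defence lists differed from each other. Of 22 NRF2 and antioxidant genes 15 rose and 5 fell, namely Cat, Prdx1, Sod2, Gsta3 and Gstm4 (camera adjusted p = 0.00179; adjusted p = 0.192 with an estimated correlation). The epoxide hydrolase gene Ephx1 rose by 1.17 ± 0.07 and the sulfiredoxin gene Srxn1 by 1.17 ± 0.08. In the unfolded protein response 5 of 23 rose and 10 fell (camera adjusted p = 0.469). The list median of -0.11 and mean of 0.04 differ in sign, as the stress factor gene Atf3 rose by 2.39 ± 0.18 while Sel1l, of protein degradation, fell by 0.32 ± 0.05. Of 27 drug metabolism genes 13 fell and 4 rose, namely Cyp3a11, Cyp2c55, Aldh1a1 and Cyp3a13 (camera adjusted p = 0.0565). Of 13 immediate early genes 7 rose and 2 fell, namely Zfp36 and Dusp1 (camera adjusted p = 0.0248; adjusted p = 0.333 with an estimated correlation, 0.0519 under quantile normalization and 0.228 with plain CPM). The transcription factor genes Klf6 (1.61 ± 0.09) and Egr2 (2.26 ± 0.15) rose. Of 13 sex-biased genes 9 fell and 3 rose, namely Mup20, Cyp4a12a and Cyp2d9 (camera adjusted p = 0.0198; adjusted p = 0.273 with an estimated correlation and 0.0654 under quantile normalization).

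Zonal, clock, blood and fat genes were examined beside these. Of 16 periportal genes 10 fell and 1, Hsd17b13, rose (camera adjusted p = 0.0181; adjusted p = 0.411 with an estimated correlation, 0.519 under quantile normalization, 0.184 at a mean of at least 50 and 0.0504 without the libraries that stood apart), and the urea cycle gene Arg1 (-0.73 ± 0.08) and the histidine lyase gene Hal (-0.96 ± 0.11) were lower. Of 15 pericentral genes 9 fell and 1, Slc1a4, rose (camera adjusted p = 0.0530), with Gulo, of ascorbate synthesis, at -0.52 ± 0.06. Of 18 clock genes 10 fell and 2 rose, namely Npas2 and Arntl (camera adjusted p = 0.0530), with Hlf at -0.94 ± 0.07 and Ciart at -1.67 ± 0.21. Of 5 erythrocyte genes 4 fell (camera adjusted p = 0.320), including the globin gene Hbb-bs (-0.81 ± 0.19). Hba-a1 fell by 0.42 ± 0.09, but not by edgeR (-0.05, adjusted p = 1) or DESeq2 (-0.35, adjusted p = 0.459). The acinar elastase gene Cela1, the only pancreatic marker tested, fell by 1.34 ± 0.10. Of 6 adipocyte markers 3 rose and 1, Car3, fell (camera adjusted p = 0.167), with the droplet gene Cidec at 1.24 ± 0.14 and the adipogenic factor gene Pparg at 1.54 ± 0.18. Counts adjusted over a list alone equalled those over all genes tested, except for the periportal list with 2 risen and 11 fallen.

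**Figure D2:**
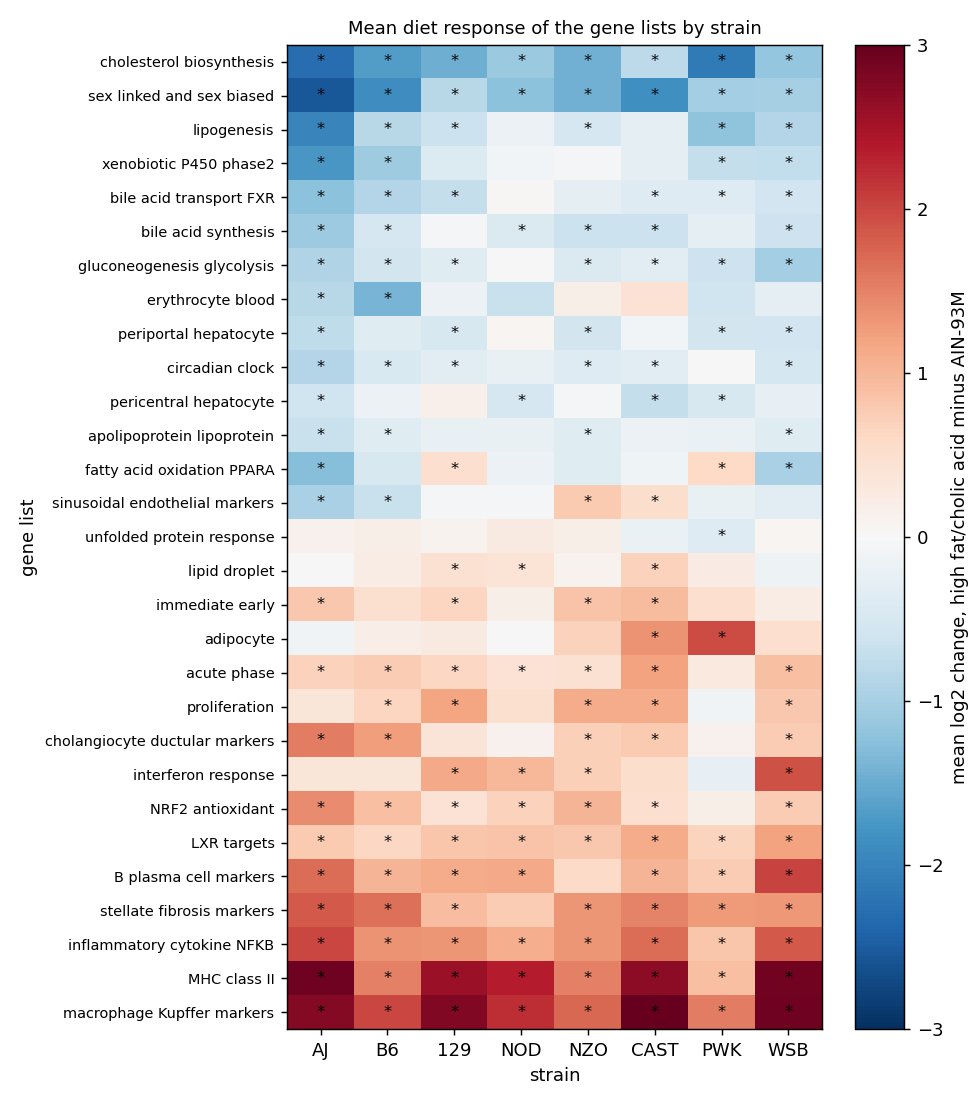
Mean log2 change (HFCA minus AIN-93M) of the tested members of 29 gene lists in each strain, as a colour scale. An asterisk marks an adjusted p under 0.05 by limma on list means (3 + 3 libraries).

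Within each strain the diet was compared in 3 + 3 mice. The SE rest on a spread shared by all groups. HFCA replicates spread by 90.9 to 133 times the counting variance in CAST and 62.3 to 129 in PWK, against 8.25 to 14.5 in NZO. The errors may therefore be too small for CAST and PWK. Gpnmb was the largest increase past the threshold in all 8 strains, from 6.00 ± 0.87 in NZO to 9.71 ± 0.87 in AJ. The largest decreases were in genes of steroid and drug metabolism and a serpin. Cyp3a16, a cytochrome P450 gene, fell by 7.42 ± 0.98 in AJ and fell by 7.36 ± 0.98 in PWK. Cyp3a41a fell by 6.68 ± 0.77 in B6, and Cyp3a44 fell by 5.35 ± 0.96 in 129 and fell by 6.72 ± 0.96 in NZO. Sult2a1, a bile acid sulfotransferase gene, fell by 5.49 ± 0.68 in WSB. Serpina4-ps1 fell by 7.82 ± 1.10 in NOD and fell by 4.90 ± 1.10 in CAST. The CAST value did not pass with that strain's own 6 libraries (adjusted p = 0.129), by edgeR (-2.13, adjusted p = 0.0973) or by DESeq2 (-2.14, adjusted p = 0.0947).

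Most genes passed in AJ, with 2742 higher and 3215 lower, followed by CAST (2502 and 2642) and WSB (2091 and 2362). PWK had 1476 and 1710, B6 1147 and 1689, NZO 1322 and 1322, 129 981 and 607 and NOD 776 and 493. In total 200 genes rose and 62 fell in all 8 strains. Single libraries moved the counts of 4 strains. B6 (2836) gave 1618 without AIN-93M replicate 1, 1148 without HFCA replicate 2 and 1428 without HFCA replicate 3, and 129 (1588) gave 859 without AIN-93M replicate 3 and 861 without HFCA replicate 3. NOD (1269) gave 665, 784 and 495 without AIN-93M replicate 3, HFCA replicate 1 and HFCA replicate 2, and 2116 without the 4 libraries of other strains that stood apart. NZO (2644) gave 1283, 1627 and 1663 without AIN-93M replicate 3, HFCA replicate 1 and HFCA replicate 3. With only the strain's own 6 libraries CAST had 614 genes, PWK 1046, NOD 2001 and NZO 4337. With plain CPM more of the genes past the threshold were higher, for example 73.2% instead of 46.0% in AJ.

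**Figure D3:**
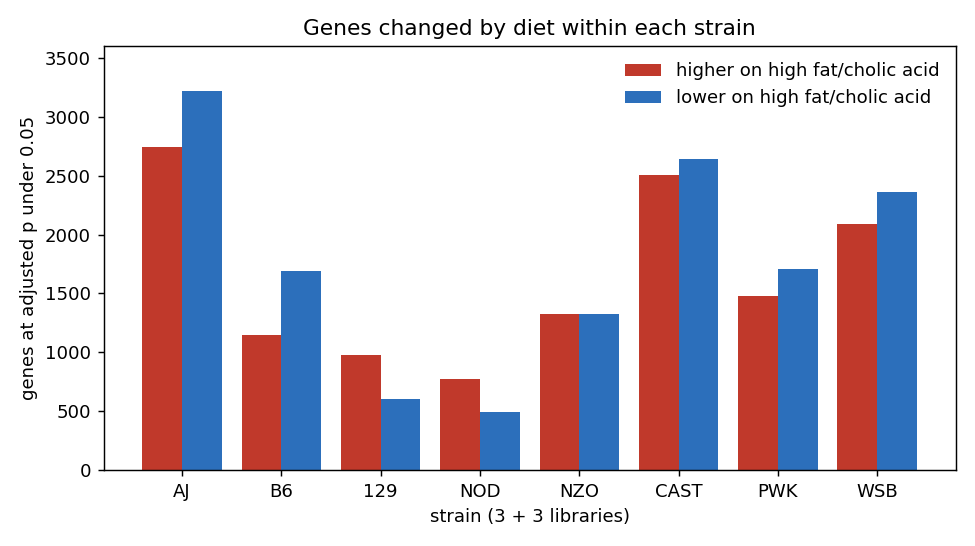
Number of genes higher or lower on HFCA at an adjusted p under 0.05 in each strain, by limma (3 + 3 libraries per strain). AJ has the most genes (5957) and NOD the fewest (1269).

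Gene groups were compared within strains by limma on list means. Camera with an estimated correlation called 0 of 232 lists within strains. Cholesterol synthesis genes were lower in all 8 strains, from -0.80 ± 0.19 in CAST with 15 of 26 members fallen to -2.28 ± 0.19 in AJ with 25 fallen. Macrophage markers were higher in all 8, from 1.55 ± 0.40 in PWK (15 of 25 risen) to 3.70 ± 0.40 in CAST (24 risen). LXR targets were higher in all 8, from 0.62 ± 0.16 in B6 to 1.21 ± 0.16 in WSB. Fibrosis markers rose in 24 of 29 cases in CAST but in 3 in NOD, where the list mean of 0.76 ± 0.36 did not pass (adjusted p = 0.0618), while the interaction of this list mean had an adjusted p of 0.477. Adipocyte markers were higher in PWK (1.95 ± 0.46) and CAST (1.35 ± 0.46), and without the libraries that stood apart their means were 0.89 ± 0.13 and 0.81 ± 0.17. That fit keeps 2 HFCA libraries of PWK and only 1 of CAST. Across the 28 pairs of strains, the diet changes of all genes tested had a median Pearson r of 0.70 (0.50 to 0.84). Genes are not independent replicates, so no p is given.

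The interaction asked whether the diet changes liver genes differently between strains. The smallest p were of genes that set PWK, AJ or WSB apart. Hsd3b3, a steroid dehydrogenase gene, rose in PWK by 3.42 ± 0.28 and fell in AJ (-1.26) and CAST (-1.01; interaction adjusted p = 2.94e-09). Cyp2d9, a male-biased cytochrome P450, rose in PWK by 4.78 ± 0.41 and fell in CAST (-1.54; adjusted p = 1.90e-08). Cyp4a14 rose by 6.12 ± 0.75 in PWK and fell in AJ (-4.04), CAST (-2.13) and WSB (-4.27; adjusted p = 8.77e-08). The complement gene C9 rose by 3.63 ± 0.25 in WSB, 0.94 in 129 and 0.65 in CAST (adjusted p = 2.14e-08). Apol9b, an apolipoprotein L gene, rose by 2.98 ± 0.30 in WSB and fell in AJ (-1.11; adjusted p = 3.94e-07).

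AJ had the deepest decreases of 4 further genes. Thrsp fell there by 6.19 ± 0.36 and in NOD changed by -1.16 (interaction adjusted p = 6.31e-08), and the macroglobulin pseudogene Mug-ps1 fell by 4.73 ± 0.30 (adjusted p = 2.39e-08). Mup3, a major urinary protein gene, fell by 6.62 ± 0.47 in AJ and changed by 0.11 in WSB (adjusted p = 1.98e-07). Mfsd2a, a lysophospholipid carrier gene, fell by 4.32 ± 0.39 in AJ and changed by -2.81 in WSB (adjusted p = 1.98e-07). The glucuronosyltransferase gene Ugt2b35 rose in AJ (0.70), NZO (0.77) and WSB (0.71) and fell in 129 (-0.60), CAST (-1.14) and PWK (-1.08; adjusted p = 8.99e-07). In all, 4229 genes passed the F test, 3354 of them with an averaged diet effect. 642 genes passed in opposite directions in different strains, 620 of them with an interaction. Leaving out 1 library gave 3446 to 5320 genes.

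**Figure D4:**
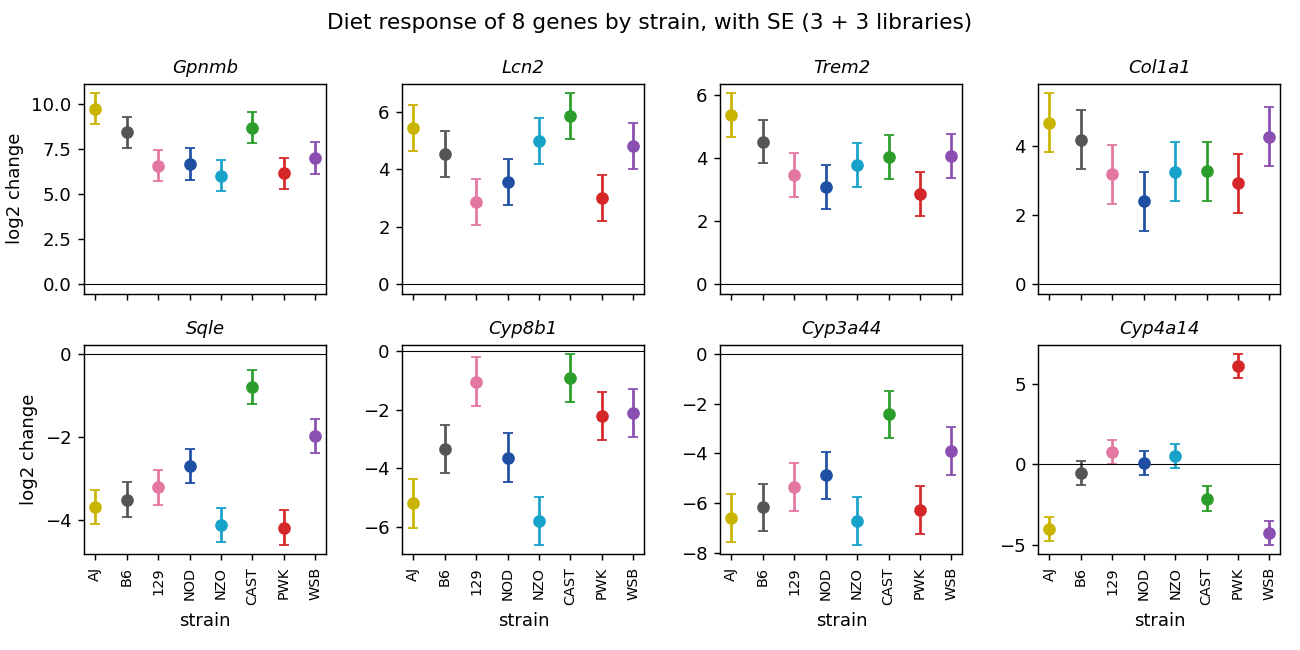
Log2 change (HFCA minus AIN-93M) of 8 genes in each strain, by limma on 3 + 3 libraries. Error bars are SE from a spread shared by all 48 libraries, not from each strain's own mice. Gpnmb rises in every strain, whereas Cyp4a14 rises by 6.12 in PWK and changes by -4.27 in WSB.

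Each strain's diet change was then set against the mean of the other 7, with lists tested by limma on their means. The diet change of interferon genes stood out in WSB and PWK. In WSB 24 of 26 rose (difference 1.35 ± 0.29, adjusted p = 0.00207), whereas in PWK 0 rose and 3 fell by limma (-1.11 ± 0.29, adjusted p = 0.00633). The strains differed before the challenge, with list means of 3.13 to 3.30 in WSB and 4.83 to 5.15 in PWK on AIN-93M. On HFCA they were 4.87 to 5.39 in WSB. In PWK they were 4.85 and 5.09 on HFCA, and 4.12 in HFCA replicate 3, which stood apart. Genes of fatty acid oxidation fell in 31 of 36 cases in AJ (-1.15 ± 0.24, adjusted p = 0.00203) and in 27 in WSB (-0.78 ± 0.24, adjusted p = 0.0188). They rose in 10 cases in PWK (1.004 ± 0.24, adjusted p = 0.00376) and in 6 in 129 (0.91 ± 0.24, adjusted p = 0.00654). Lipogenesis fell more in AJ (-1.34 ± 0.22, adjusted p = 7.25e-05), and in NOD, where the list did not pass (-0.19 ± 0.20, adjusted p = 0.422), it differed the other way (0.72 ± 0.22, adjusted p = 0.0173). Cholesterol synthesis fell more in AJ (-0.89 ± 0.21, adjusted p = 0.00356) and PWK (-0.70 ± 0.21, adjusted p = 0.0152) and less in CAST (0.81 ± 0.21, adjusted p = 0.00587). The list means on AIN-93M were 4.93 to 5.33 in CAST and 6.48 to 6.67 in AJ. On HFCA they were alike, at 4.18 to 4.44 in CAST and 4.21 to 4.42 in AJ. Without the libraries that stood apart the CAST difference was 0.70 ± 0.28 (adjusted p = 0.0632), with 1 HFCA library left and a larger error. Sinusoidal endothelial markers fell in 12 of 17 cases in AJ (-0.97 ± 0.24, adjusted p = 0.00530) and rose in 8 in NZO (1.03 ± 0.24, adjusted p = 0.00356). Their list means on AIN-93M were lowest in NZO, at 4.35 to 4.98, against 4.98 to 6.51 in the other strains. On HFCA they were 5.37 to 5.64 in NZO and 4.45 to 6.05 in the others. In PWK the changes of MHC class II genes (-1.45 ± 0.42, adjusted p = 0.0144), proliferation genes (-0.92 ± 0.26, adjusted p = 0.0105) and NRF2 genes (-0.64 ± 0.17, adjusted p = 0.00650) lay below the mean of the others. The last 2 lists did not pass in PWK (means -0.10 ± 0.24 and 0.18 ± 0.16). PWK HFCA replicate 3, which stood apart, had the lowest list means of its group. They were 4.35, 3.97 and 5.72, against 4.91 to 5.14, 4.32 to 4.35 and 6.10 to 6.11 in the other PWK HFCA libraries. Camera with an estimated correlation called 0 of 232 such list differences, with 19 at an unadjusted p under 0.05. The preset correlation called 86, fry 37 and list means 38.

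Single genes past the threshold in this comparison numbered 2430 in AJ (975 more positive, 1455 more negative), 1747 in CAST (929 and 818), 1323 in PWK (656 and 667) and, in WSB, 449 more positive and 298 more negative. NOD had 184, NZO 148, 129 39 and B6 28. Without the 4 libraries that stood apart these last strains had 693, 505, 658 and 115. Single libraries moved these counts. AJ gave 1297 without AJ HFCA replicate 2. Counts for B6 were 5 without B6 HFCA replicate 3, 10 without B6 AIN-93M replicate 3, 11 without B6 HFCA replicate 2, 15 without B6 AIN-93M replicate 2, 18 without B6 AIN-93M replicate 1 and 58 without B6 HFCA replicate 1. In 129 there were 9 without 129 AIN-93M replicate 2, 12 without 129 AIN-93M replicate 3, 13 without 129 HFCA replicate 1, 13 without 129 HFCA replicate 3, 14 without 129 HFCA replicate 2, 25 without B6 AIN-93M replicate 2, 65 without PWK HFCA replicate 3, 126 without B6 HFCA replicate 1 and 227 without CAST HFCA replicate 3. NOD gave 63 without NOD HFCA replicate 1, 64 without NOD AIN-93M replicate 1, 85 without NOD HFCA replicate 3, 98 without NOD AIN-93M replicate 2, 120 without NOD HFCA replicate 2 and 363 without CAST HFCA replicate 3. Counts for NZO were 52 without NZO AIN-93M replicate 3, 58 without NZO HFCA replicate 3, 63 without NZO HFCA replicate 1, 71 without NZO HFCA replicate 2, 76 without NZO AIN-93M replicate 1 and 223 without CAST HFCA replicate 3. In CAST there were 973 without CAST AIN-93M replicate 2. PWK gave 738 without PWK AIN-93M replicate 2. Counts for WSB were 237 without WSB AIN-93M replicate 3, 322 without WSB HFCA replicate 1, 342 without WSB AIN-93M replicate 1, 352 without WSB HFCA replicate 3 and 1140 without WSB AIN-93M replicate 2.

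Strain differences without the challenge were read from the AIN-93M libraries, with each strain set against the mean of the other 7. Among the largest differences of single strains were those of cytochrome P450, sulfotransferase and serpin genes, an interferon-induced gene and a splicing factor gene. Cyp2b9, a female-biased cytochrome P450, was lower in 129 (-8.27 ± 0.46), where its mean was 0.466, and the glutathione transferase gene Gstm3 was higher there (2.63 ± 0.40) and lower in NZO (-3.15 ± 0.40). Cyp2b13 was higher in B6 (2.86 ± 0.45) and NOD (4.31 ± 0.45), and Cyp2c39 was lower in B6 (-5.32 ± 0.20). The antitrypsin gene Serpina1e was lower in NOD (-4.67 ± 0.52) and WSB (-4.51 ± 0.52) and higher in CAST (6.73 ± 0.52), and Serpina1c was lower in PWK (-8.06 ± 0.17). Iigp1, an interferon-induced GTPase gene, was lower in CAST (-8.74 ± 0.29), with a mean of 0.168. Cwc22, a splicing factor gene, was higher in WSB (5.72 ± 0.11), with a mean of 928 against 13.3 to 19.4 in the others. The actin-binding gene Gsn was higher in PWK (4.57 ± 0.38), A1bg in NZO (4.78 ± 0.71) and Apol9b in AJ (2.99 ± 0.23), while Sult3a2 was lower in AJ (-5.05 ± 0.49). Sequence differences from the reference build can lower read assignment in a strain, most so in CAST and PWK, and were not separated from expression.

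The F test of strain called 9086 genes on AIN-93M and 9280 on HFCA. Against the other 7 on AIN-93M, CAST had 5898 genes, PWK 4542, WSB 4030, NZO 3228, B6 2818, AJ 2254, NOD 2168 and 129 2077. B6 gave 1613 without B6 AIN-93M replicate 2 and 1838 without B6 AIN-93M replicate 3. Counts for 129 were 1152 without 129 AIN-93M replicate 2. In NOD there were 1288 without NOD AIN-93M replicate 1 and 1361 without NOD AIN-93M replicate 2. NZO gave 1940 without NZO AIN-93M replicate 3. Counts for WSB were 2528 without WSB AIN-93M replicate 1. As checks of the labels, Xist, the silencing RNA of the inactive X, was at 1045 to 1431 in the strains on AIN-93M, and Ddx3y of the Y chromosome had at most 1 read in a library. Nnt, fixed as a check of B6, was at most 1.89 in every strain and tells nothing about the label.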

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

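The interaction F tests were fixed before the data were examined, while the tests of list means, of tissue genes, of the libraries that stood apart and of sex-biased genes in this part were chosen only after the result was seen. Liver genes that differed between strains in their diet response were singled out by the interaction test, 4229 of 10917 (38.7%) and 72 of the 103 named genes. The rule for named genes took 10 of them for their small interaction p, and others for large diet or strain effects. The count of 72 is therefore no result about the named genes. The adjusted p of the 10 named for the interaction were Hsd3b3 (2.94e-09), Cyp2d9 (1.90e-08), C9 (2.14e-08), Mug-ps1 (2.39e-08), Thrsp (6.31e-08), Cyp4a14 (8.77e-08), Mup3 (1.98e-07), Mfsd2a (1.98e-07), Apol9b (3.94e-07) and Ugt2b35 (8.99e-07). Hsd3b3, Cyp2d9 and Cyp4a14 are genes of steroid and fatty acid metabolism that rose in PWK, and C9 and Apol9b are defence genes with their largest increase in WSB.

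Of 29 list means 24 had an interaction with an adjusted p under 0.05. The smallest values were for lipogenesis (7.51e-05), fatty acid oxidation (7.51e-05), cholesterol synthesis (0.000243), sinusoidal endothelium (0.000353), glucose metabolism (0.000376), bile acid transport (0.000452), drug metabolism (0.000452) and NRF2 targets (0.000452). Values between followed for the interferon response (0.000510), the clock (0.00653), cholangiocytes (0.00792), sex-biased genes (0.00794), MHC class II (0.00798), proliferation (0.0108), macrophages (0.0159) and the unfolded protein response (0.0198). The others were B and plasma cells (0.0282), erythrocytes (0.0341), pericentral hepatocytes (0.0347), periportal hepatocytes (0.0347), bile acid synthesis (0.0364), the acute phase (0.0495), lipid droplets (0.0496) and adipocytes (0.0496).

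Genes of fat, adrenal and muscle tissue were high in single HFCA libraries, above every AIN-93M library. Muscle and adrenal genes were also raised, to lower values, in single AIN-93M libraries. In PWK HFCA replicate 3 the adipocyte genes Adipoq and Plin1 were at 137 and 208, and the steroidogenic genes Star and Cyp11b1 at 2649 and 1239. In CAST HFCA replicate 2 the muscle genes Myh4 and Ckm were at 733 and 666 and Star at 211. Adipoq and Plin1 were also at 20.6 and 31.6 there, and at 4.74 and 1.52 in B6 HFCA replicate 1. The highest AIN-93M values were 0.320 for Adipoq, 0.328 for Plin1, 8.99 for Star, 0.853 for Cyp11b1, 11.2 for Myh4 and 20.9 for Ckm. The acinar gene Ctrb1 was at 10.3 in CAST HFCA replicate 3 and 8.14 in NOD HFCA replicate 2, against at most 0.334 on AIN-93M. The genes named so far were below the filter of the tests, but others of these tissues passed it and were among the 10917 tested. They include the muscle genes Acta1 and Myh1, at 2529 and 2358 in CAST HFCA replicate 2. In PWK HFCA replicate 3 the adrenal genes Cyp21a1 and Hsd3b1 were at 1719 and 2065, and the adipocyte gene Cfd was at 102. On AIN-93M, Acta1 and the muscle gene Ttn were at 84.0 and 87.7 in CAST replicate 1. They were at 30.7 and 30.8 in 129 AIN-93M replicate 2, against medians of 0.0421 and 0.607 over all libraries. Cyp21a1 was at 11.2 in NZO AIN-93M replicate 1, against a median of 0.218. The fit without the 4 libraries that stood apart keeps these AIN-93M libraries.

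Of 21 tissue genes, 3 were above the strain's highest AIN-93M library in every HFCA library of PWK or CAST. The adrenal and muscle genes among them were chosen after their values in single libraries were seen, so a low count was likely beforehand. It shows that most of these genes were not raised in all 3 mice of a group, but it cannot test a liver response. Adipose tissue carried over into PWK HFCA replicate 3 is a candidate explanation, as 5 of the 5 adipocyte genes that stay at or below 1 in every AIN-93M library were at least 10 times as high as in the other PWK HFCA libraries. Of the adipocyte genes with higher values on AIN-93M, Car3, Pparg and Cidec were not. For adrenal tissue carried over into it, 6 genes kept their proportions to CAST HFCA replicate 2 (7.80 to 12.8 times, a spread of 1.64). For skeletal muscle carried over into CAST HFCA replicate 2, 10 genes were 26.3 to 65.3 times those of CAST AIN-93M replicate 1, a spread of 2.48. Dissection of neighbouring tissue may account for these genes. The averaged list means of macrophage markers and cholesterol synthesis were 2.66 and -1.54 without the 4 libraries that stood apart, against 2.46 and -1.50 with them, so these averaged changes do not rest on those libraries.

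B6 HFCA replicate 1 and CAST HFCA replicate 3 lay nearest to AIN-93M libraries. A wrong label is argued against by genes that rose in the other 7 strains, of which 96.8% (210 of 217) in the B6 library and 90.05% (190 of 211) in the CAST library were above all 3 AIN-93M libraries of the strain, against 25% by chance. A mixture of AIN-93M RNA with RNA like that of the other 2 libraries would give rising and falling genes the same share of the full change. Median shares were 0.315 and 0.751 in B6, a difference of 0.437, and 0.152 and 0.769 in CAST, a difference of 0.617, which argues against it. List means of NF-kappaB and cytokine genes were lower in these libraries than in the others of their groups. They were 4.43 against 5.54 and 5.42 in B6, and 3.46 against 5.38 and 4.94 in CAST. Macrophage marker means were 6.23 against 7.41 and 6.75 in B6, and 4.88 against 7.01 and 6.44 in CAST. A weaker inflammatory response of these 2 mice as the reason for their position stays open and was not tested.

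The female-biased genes Cyp3a44, Sult3a1, A1bg and Cyp2b9 fell. For Cyp3a44 (-5.29 ± 0.34), Sult3a1 (-3.66 ± 0.27) and A1bg (-3.50 ± 0.33) a lower share of hepatocyte RNA is argued against as the whole cause, since their changes lie below most of those of the 100 most abundant genes on AIN-93M (median -0.48, 5% to 95% of them -1.02 to 0.13). These 3 genes were named for being among the 5 largest decreases, so their values cannot speak for female-biased genes as a set. For Cyp2b9 (-1.06 ± 0.22) a lower share of hepatocyte RNA stays open. A shift toward the male pattern of liver genes stays open, because of 7 male-biased genes 3 fell (Hsd3b5, Mup3 and Cyp7b1) and 3 rose (Mup20, Cyp4a12a and Cyp2d9). The rise of Cyp2d9 rests on PWK (4.78), the only strain in which it rose, and it fell in CAST (-1.54). Bile acids and hormones were not measured, and inflammation was not tested as a cause.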

How the results depend on the processing

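Plain CPM, the filter of at least 1 in 3 libraries, the fit without 4 libraries that stood apart and limma on list means were chosen after seeing the data; all other settings were fixed before. Of 125 values of named genes, 118 passed or missed the test alike, called ones in the same direction, in each of the 60 to 62 settings in which they were fitted. Uncalled values changed sign in 4 further cases, for example Scd1, which ran from -0.17 to 0.24. Cpt1a, uncalled at -0.04, rose by 0.28 under quantile normalization (adjusted p = 0.000660), the only reversal with a call. Quantile normalization gave Cyp7a1 0.61, Plin2 0.48 and Abcb11 -0.09, and plain CPM gave Cyp7a1 0.67 and Plin2 0.36. Hba-a1 was at -0.05 by edgeR and -0.35 by DESeq2, and Serpina4-ps1 in CAST at -2.13 and -2.14, and -4.90 on its own 6 libraries. With libraries left out 1 at a time, Cyp7a1 ran from 0.39 to 0.58, Plin2 from 0.09 to 0.24 and Cyp4a14 from -0.56 to -0.32.

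The averaged diet count of 7848 was 7767 by edgeR (7216 shared), 7934 by DESeq2 (7660 shared), 7998 under quantile normalization (6640 shared) and 8003 with plain CPM (5775 shared, 5651 with the same sign). With the replicate number as a block it was 7841, and this block moved no count by more than 1.5 times. The numbers do not pair the libraries, as the 24 correlations of same-numbered libraries had a median of -0.00216.

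Without a filter the counts that moved by more than 1.5 times were averaged diet 13466, AJ diet 9162, AJ on AIN-93M 3904, B6 against others 100, 129 against others 100, 129 on AIN-93M 3154, NZO against others 231, CAST on AIN-93M 9831, PWK on AIN-93M 7496, strain on AIN-93M 15676 and strain on HFCA 16977. With a filter of a mean of at least 50 (3922 genes) they were averaged diet 2911, AJ diet 2291, AJ against others 1152, AJ on AIN-93M 7.4e+02, B6 diet 1245, B6 against others 0, B6 on AIN-93M 768, 129 diet 448, 129 against others 15, 129 on AIN-93M 600, NOD diet 395, NOD against others 94, NOD on AIN-93M 650, NZO diet 1008, NZO against others 40, NZO on AIN-93M 1095, CAST diet 1719, CAST against others 613, CAST on AIN-93M 2050, PWK diet 1229, PWK against others 508, PWK on AIN-93M 1568, WSB diet 1737, WSB against others 252, WSB on AIN-93M 1376, interaction 1705, strain on AIN-93M 3227 and strain on HFCA 3355. The count of 0 for B6 by limma compares with 274 genes at an unadjusted p under 0.05, and with 8 by edgeR and 43 by DESeq2 under the filter of the report. With the filter of at least 1 they were B6 against others 58, 129 against others 62 and NZO against others 231. Quantile normalization moved 129 against others 87, edgeR B6 against others 8 and 129 against others 17 and DESeq2 B6 against others 43, 129 against others 145 and NZO against others 225. On their own 6 libraries the moved counts were NOD diet 2001, NZO diet 4337, CAST diet 614 and PWK diet 1046. Without the 4 libraries that stood apart they were B6 against others 115, 129 against others 658, NOD diet 2116, NOD against others 693 and NZO against others 505.

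Of the 29 lists camera called 20 at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Fry called 27 and limma on list means 27. Within strains the counts were 142 and 0 of 232 (41 unadjusted), and 151 and 158 by fry and list means. Against the other strains they were 86, 0 (19 unadjusted), 37 and 38. Camera called 14 lists under quantile normalization, 14 at a mean of at least 50, where some lists had too few members, and 21 with plain CPM, and the report names the lists that lost their call. Lists that gained one were bile acid transport (0.0494) and clock genes (0.0494) with a pseudocount of 5, bile acid transport (0.00226), lipid droplets (0.0458), drug metabolism (0.000541), pericentral genes (0.000415) and clock genes (0.00221) without a filter, lipid droplets (0.0209) at a mean of at least 50, bile acid transport (0.0392), drug metabolism (0.0280) and pericentral genes (0.0169) without the libraries that stood apart, bile acid transport (0.00259), drug metabolism (0.00158), pericentral genes (0.00507) and clock genes (0.00420) with plain CPM and bile acid transport (0.0297), drug metabolism (0.0155), pericentral genes (0.0145) and clock genes (0.0301) with the filter of at least 1. Leaving out 1 library ended no call of a list. It gave a call to bile acid transport, drug metabolism, pericentral or clock genes in several cases, and to all 4, which makes 24 lists, without AJ HFCA replicate 1, NZO HFCA replicate 2, CAST HFCA replicate 3 or WSB HFCA replicate 2. By list means the unfolded protein response passed at a mean of at least 50 (-0.22), under quantile normalization (0.14) and with plain CPM (0.22), and sinusoidal markers passed at a mean of at least 50 (-0.20). The mean of the unfolded protein response was -0.01 with a pseudocount of 5.

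Leaving out 1 library moved diet counts within strains over the ranges B6 1148 to 3505, 129 859 to 1898, NOD 495 to 1654 and NZO 1283 to 3050. Against the other strains the ranges were AJ 1297 to 2703, B6 5 to 58, 129 9 to 227, NOD 63 to 363, NZO 52 to 223, CAST 973 to 2579, PWK 738 to 1765 and WSB 237 to 1140. On AIN-93M they were B6 1613 to 3208, 129 1152 to 2331, NOD 1288 to 2454, NZO 1940 to 3579 and WSB 2528 to 4336. The libraries behind the lowest counts are named in the report. Those behind the highest counts are named there only in part.

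Median shares of variation were 42.4% (strain), 17.3% (diet), 11.05% (interaction) and 19.96% (residual) for genes with a mean of at least 100. With a pseudocount of 5 they were 44.9%, 11.5%, 10.6% and 21.2%. The median correlation between strains was 0.638 by rank and 0.686 for genes with a mean of at least 100.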

Other observations

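Sums over families of nearly identical genes do not depend on which member a read was given to. Reads left out because they match several members would be missing from the sums as well, and how such reads were handled is not given in the sources used here. Major urinary protein genes summed to 1504 in AJ on AIN-93M and 40.6 on HFCA, but to 175 and 207 in PWK and 649 and 656 in WSB. The Sult3a sulfotransferase genes went from 58.6 to 0.547 in AJ and from 2213 to 820 in CAST, and the Sult2a genes from 887 to 24.2 in AJ. The Cyp3a genes together went from 3556 to 6316 in NOD and from 3398 to 2203 in AJ, although Cyp3a44 fell in both. These are means of 3 + 3 libraries without a test, chosen after the values were seen.

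Some genes were near 0 in all libraries of a strain. Between 25 (129) and 36 (PWK) genes were below 1 in all 6 libraries of a strain, with a mean of at least 10 over the libraries of the other strains. A gene can meet this rule while near 0 in several strains, and is then counted in each of them. The alpha globin gene Hba-a1 had a mean of 0 in AJ, NZO and WSB and 0.0276 in CAST, against 31.6 in B6, 45.6 in 129, 109 in NOD and 97.2 in PWK. Hba-a2 was above 1 in B6 (11.2) and 129 (17.1) only. Read assignment and expression were not separated here, and such values are not evidence of a missing gene.

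Other splits of the same libraries were counted, with tests chosen only after the result was seen. Of 100 splits that reassign diet within strains, the real one included, 1 gave as many genes as the averaged diet effect (7848 against 1449 in the highest other split), which excludes chance. Such splits remove the diet effect itself, so they cannot test whether strains differ in it. For that the strain effects and the averaged diet effect were kept, and the residuals were reassigned among the libraries of each diet. Chance is then excluded for the interaction (1 of 100, 4229 against 1). It is also excluded, at 1 of 100 each, for the diet response against the other strains in AJ (2430 against 250), NZO (148 against 20), CAST (1747 against 157), PWK (1323 against 52) and WSB (449 higher plus 298 lower against 123). The share was under 0.05 in B6 (2 of 100, 28 against 51), 129 (3 of 100, 39 against 593) and NOD (2 of 100, 184 against 211). A reassignment gave more genes than the real groups there, in 129 many more, so chance is not excluded in these 3 strains.

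For the strains on AIN-93M, chance is excluded, at 1 of 100 each, in AJ (2254 against 1350), B6 (2818 against 1616), NOD (2168 against 1455), NZO (3228 against 2962), CAST (5898 against 3028), PWK (4542 against 2118) and WSB (4030 against 1573). In 129 the share was under 0.05 (2 of 100, 2077 against 2190), but a split gave more genes than the real groups, so chance is not excluded there. It is excluded for the strain F tests on AIN-93M (1; 9086 against 2546) and HFCA (1; 9280 against 3978). For lists by camera on average the share was under 0.05 (3 of 100, 20 against 23), but another split called more lists, so chance is not excluded. It is excluded within strains (1 of 100, 142 against 109), but not for lists of 1 strain against the others (11 of 100, 86 against 100). Camera at the preset correlation called many lists in arbitrary groups too, with medians of 8, 80 and 68 in these 3 comparisons, so single lists called by it alone carry little weight. By limma on list means, with medians of 0, chance is excluded on average (1; 27 against 17), for the interaction (1; 24 against 5) and against the other strains (1; 38 against 1).

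Within a strain 3 + 3 libraries make 10 splits, too few for a share under 0.05. The real count and the highest other were 5957 against 18 in AJ, 2836 against 4 in B6, 1588 against 5 in 129, 1269 against 1 in NOD, 2644 against 0 in NZO, 5144 against 4007 in CAST, 3186 against 20 in PWK and 4453 against 10 in WSB, with 1 split as large in each.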
